A study of Mus musculus with 4 samples.

How the data were processed

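Stranded, ribosomal RNA-depleted, paired-end RNA-seq libraries were made from total RNA of mouse embryonic stem cells carrying a conditional Exosc3 knockout, per the labels' protocols. RNA had a RIN of at least 8.5, per the labels' protocols. The 4 libraries form 2 groups of 2 by their titles: Exosc3-present (doxycycline kept) and Exosc3-depleted (doxycycline removed for 3 days). No group separates doxycycline from Exosc3.

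The authors deposited 1 table with 22883 rows, each with a UCSC known gene identifier, a symbol and FPKM values in 4 sample columns, per the file headers. The submitters' processing notes name the mm9 build and the tools Bowtie2, STAR, Picard, bedtools and edgeR, without versions or the role of each, so the step that made the FPKM values is not recorded. The design assumed this unit, and the main test used no counts. Because FPKM is a whole fragment count divided by model length and by a library total, both were recovered from the spacing of the values. All 15471 rows above 0 came out as whole fragments, with whole-base lengths (median 2494 bases in tested rows). The tolerance was 0.004 of a fragment, and wider at the highest counts. The shortest length that fitted was kept from a wide range. For rows above 0 in only 1 or 2 libraries some fit was nearly certain, so their lengths and counts are not secured. In simulated values the method found 95.8% of lengths exactly over 1000 genes, and 99.2% exactly or as a whole fraction. These genes were drawn only from rows with a mean FPKM of at least 0.5. Of the lengths of tested rows 33.6% were multiples of 3, so the models include untranslated regions. Of the recovered per-million totals, 49.7%, 51.8%, 42.4% and 44.0% lay in listed models in the order Exosc3-present 1 and 2, Exosc3-depleted 1 and 2. On a model of 1 kb, 1 fragment equals 0.0164, 0.0181, 0.0262 and 0.0238 FPKM. The 50 highest rows held 45.4%, 44.0%, 52.4% and 54.4% of the summed FPKM. Recovered fragments served depth, thinning, limma-voom, scaling to fragments within listed genes and the spread set in the simulation of the test. The shares inside and outside listed models and the counts of rows too low to be tested also rest on them. They did not enter the main test.

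The main test was limma 3.58.1 (R 4.3.3) with an intensity trend on log2(FPKM + 0.5), over 9336 rows with a mean FPKM of at least 0.5, with no covariate. Log2 fold changes are on this scale, which understates the change of low genes, and values given as N-fold are ratios of mean FPKM. P-values are two-sided and Benjamini-Hochberg adjusted, with a threshold of 0.05. The prior had 4.98 degrees of freedom beside 2 residual ones. On simulated data for this comparison (8899 genes run) the test recovered 1.5% of genes changed 1.5-fold, 7.5% of those changed 2-fold and 90.9% of those changed 4-fold, with 1 false call, or 1.5% of calls. The simulation changed only 67, 67 and 66 genes at these sizes, whereas 42.7% of rows were called in the real data. The adjustment was therefore stricter in the simulation, and these shares do not give the power or the false calls of the real test. A gene that did not pass is still not shown to be unchanged.

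The tests, 32 gene lists, main settings and rules for named genes were fixed before the data were examined. Named genes are the tested exosome members, the 12 largest rises and 12 largest falls with adjusted p under 0.05, mean FPKM of at least 2 and no overlap between groups, and the 4 members with the smallest p in each list. Other genes named as examples, such as members that did not pass or went against their list, were chosen after their values were seen. A symbol with several rows was represented in a list by its highest row among those that passed the filter in use. Lists with at least 5 tested members (30 lists) were tested with camera at a preset inter-gene correlation of 0.01, which compares a list with all other tested rows, and adjusted over the lists. With an estimated correlation 0 of the 18 called lists passed, the lowest adjusted p being 0.339; that test has 2 residual degrees of freedom. Counts of list members are given over all tested rows and adjusted over the list alone. List medians "relative to the median row" subtract the median of all tested rows.

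Biotypes and gene spans came from annotation of the GRCm38 assembly, matched by symbol (95.5% of tested rows matched, 961 of them through an older symbol). That assembly differs from mm9, so no coordinates are given, and spans are properties of a gene only. Rows with no match (417 tested) were left out of the coding and noncoding comparison, which used Fisher's exact test with 95% intervals. Matched coding rows were drawn as up to 10 per noncoding row by mean FPKM.

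Alternatives covered the pseudocount, the filter, scaling (median of ratios, quantile, without the 50 highest rows), robust and untrended fits, other thresholds, other set tests, the replicate number as a block, and each library left out in turn, when the lone library of a group is assumed to vary like the other group. Chosen after seeing the data were limma-voom, scaling to fragments within listed genes, removal of a length trend from each library, a filter on the Exosc3-present libraries for gene lists, with matching for noncoding rows and rows with no match, and the exosome and cofactor lists without Exosc3 or Mpp6. Tests of splits of the samples were not run because each group has 2 libraries. Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were also used.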

Results

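Total RNA was sequenced from mouse embryonic stem cells in which Exosc3, a core subunit of the RNA exosome, depended on doxycycline in the medium. The RNA exosome is the 3′-to-5′ ribonuclease complex that processes and degrades many nuclear and cytoplasmic RNAs. Conditional knockout clones of the V6.5 line were kept in 0.1 µg/ml doxycycline (Exosc3-present) or grown without it for 3 days (Exosc3-depleted), and each group had 2 libraries. The libraries were stranded and depleted of ribosomal RNA. The table gave 22883 gene models as FPKM, which divides fragments by model length and library total. The per-million total was 60851774 and 55233386 fragments in the Exosc3-present replicates 1 and 2, and 38095698 and 41968325 in the Exosc3-depleted replicates 1 and 2. Of these, 30253508, 28610454, 16150958 and 18483137 fragments lay in listed gene models. A tested row had a median of 777, 745, 376 and 493 fragments, so counting error was small for most named genes. The labels do not say whether replicates were separate cultures, so each p-value measures only the spread between these samples, which could be technical. Doxycycline and Exosc3 changed together in every comparison.

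The first comparison asked whether Exosc3 RNA was lost, and what happened to the other parts of its complex. Exosc3 (uc008ssk.1) fell 35.8-fold, from 23.7 ± 0.70 FPKM (SD, n = 2) in Exosc3-present cells to 0.663 ± 0.040 (n = 2) in Exosc3-depleted cells. Single libraries held 1524 and 1327 Exosc3 fragments against 25 and 30. The log2 fold change was -4.38 (SE 0.18, limma adjusted p = 0.000129), so the labels matched the depleted gene in all 4 libraries. The exosome list has 14 members, of which 10 had a row and were tested. Exosc4, Exosc6, Exosc9 and the nuclease gene Dis3 had no row under those symbols, so nothing is known of them here. Of the 10 tested members 6 fell and none rose, and the same 6 passed in the count adjusted over the list alone. Exosc7, a subunit of the hexameric ring, fell from 43.6 ± 2.2 to 14.7 ± 2.5 FPKM (log2 -1.55), and Dis3l, a cytoplasmic exosome nuclease, fell from 10.3 ± 0.60 to 3.03 ± 0.97 (log2 -1.64). Exosc2, a cap subunit like Exosc3, fell by 1.01 on the log2 scale, Exosc8 fell by 0.95, and Mphosph6, a nuclear exosome cofactor, fell by 1.09. Under the other scalings 5 to 6 of the 10 members were called lower. Exosc1 (log2 -0.40), Exosc5 (-0.13), the nuclear nuclease Exosc10 (0.07) and its partner C1d (0.13) did not pass; Exosc5 took a positive sign under 5 other scalings and Exosc10 and C1d changed sign when single libraries were left out. As a group the list was lower than other genes (camera adjusted p = 0.0354; adjusted p = 0.369 with an estimated correlation), but it includes Exosc3, whose loss the design set. The other 9 members, of which 5 fell, did not pass as a group (camera adjusted p = 0.104), so a fall of the rest of the complex as a whole was not shown. The call of the full list also ended without Exosc3-depleted replicate 2 (adjusted p = 0.102), with quantile normalization (0.0649), with the filter at a mean FPKM of 2 (0.0656) and with a filter on the Exosc3-present libraries alone (0.067), and 3 members passed without Exosc3-present replicate 2, when Exosc2 (adjusted p = 0.0566), Exosc8 (0.0955) and Mphosph6 (0.0884) did not.

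**Figure D1:**
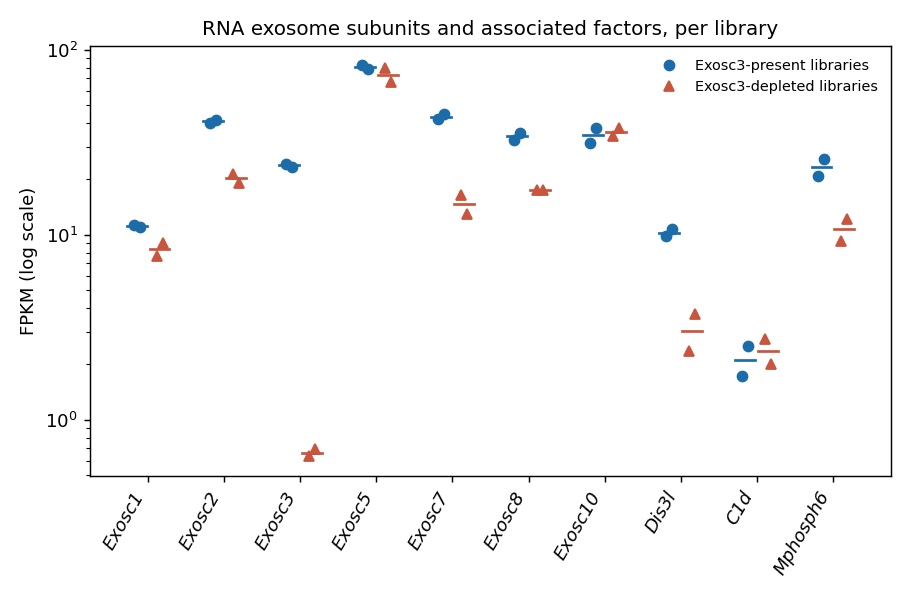
FPKM on a log axis of the 10 tested exosome genes; blue circles are the Exosc3-present and red triangles the Exosc3-depleted libraries, with a line at each mean of 2. Exosc3 sits at 24.2 and 23.2 FPKM against 0.635 and 0.691, while the values of Exosc5, Exosc10 and C1d overlap between groups.

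Across the transcriptome, Cyr61 (uc008rqq.2), a secreted matricellular protein, had the largest rise on the log2(FPKM + 0.5) scale by which genes were ranked, from 1.73 ± 0.18 to 84.8 ± 10.5 FPKM (49.1-fold as a ratio of means; log2 5.26, SE 0.19, adjusted p = 0.000111). Chac1 (uc008lts.2), a glutathione-degrading enzyme, had the largest fall on that scale, from 34.2 ± 3.2 to 0.565 ± 0.018 FPKM (60.6-fold; log2 -5.02, SE 0.18, adjusted p = 0.000111). Of 9336 tested rows, 3983 changed, 1177 upward and 2806 downward; 4801 had an unadjusted p under 0.05. The median tested row was at log2 -0.27, so most small falls lay near the level of a typical gene. Some list medians are also given relative to it. Of protein-coding rows 30.8% fell and 11.1% rose, and counts of list members below are to be read beside these shares. After median-of-ratios scaling, which set the median row to 0.01, 1756 rows were higher and 1589 lower, so 52.5% of changed rows were higher in place of 29.6%. Quantile normalization gave 47.0% higher, scaling without the 50 highest genes 53.7%, scaling to fragments within listed genes 45.2% and removal of a length trend 51.4%. The Exosc3-depleted pair differed more (SD of the log2 difference 0.432) than the Exosc3-present pair (0.188). A fit with 1 library left out takes its residual variance from the pair of the other group. Calls gained or lost in such fits, here and below, therefore partly follow that unequal spread and not only the library left out. With 1 library left out the number of changed rows was 2033 without Exosc3-present replicate 1, 1750 without Exosc3-present replicate 2, 5973 without Exosc3-depleted replicate 1 and 6334 without Exosc3-depleted replicate 2. The 4801 rows at an unadjusted p under 0.05 and these shifts make single small changes uncertain, whereas the genes named for size passed under every scaling and with each library left out.

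Among the other largest rises, Fgfbp1, a secreted carrier of fibroblast growth factors, went from 0.290 to 26.3 FPKM (log2 5.05), and the carboxypeptidase Cpz from 0.252 to 20.4 (4.79). The calcium-binding protein S100a6 rose from 8.18 to 222 FPKM (4.66), Ms4a10 rose by log2 4.57, the leukotriene receptor gene Ltb4r2 by 3.94, Gm9949 by 3.71, and the homeobox gene Nkx2-9 by 3.61. Gm4340 (4.38) and Zscan4f (3.67), both marks of the 2-cell-like state, and Perp (3.69) and Plk2 (3.64), both p53 targets, completed the 12 largest rises. Among the largest falls after Chac1 and Exosc3, Pck2, the mitochondrial phosphoenolpyruvate carboxykinase, fell from 31.4 to 1.28 FPKM (log2 -4.18), the mitochondrial folate enzyme Mthfd2 from 35.4 to 2.85 (-3.42), and the serine synthesis enzyme Psat1 from 190 to 18.5 (-3.34). The stress-induced nuclear protein Nupr1 fell by 4.18 on the log2 scale, the RNA helicase Mov10 by 3.77, and Rpl22l1, a paralogue of a ribosomal protein, by 3.52. The activin subunit Inhbb fell by 3.34, the hexosamine pathway enzyme Gfpt2 by 3.28, the mitophagy receptor Bnip3 by 3.12 and the glutathione hydrolase Ggt1 from 6.12 to 0.275 FPKM. The 24 genes had adjusted p-values between 0.000111 and 0.000388.

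**Figure D2:**
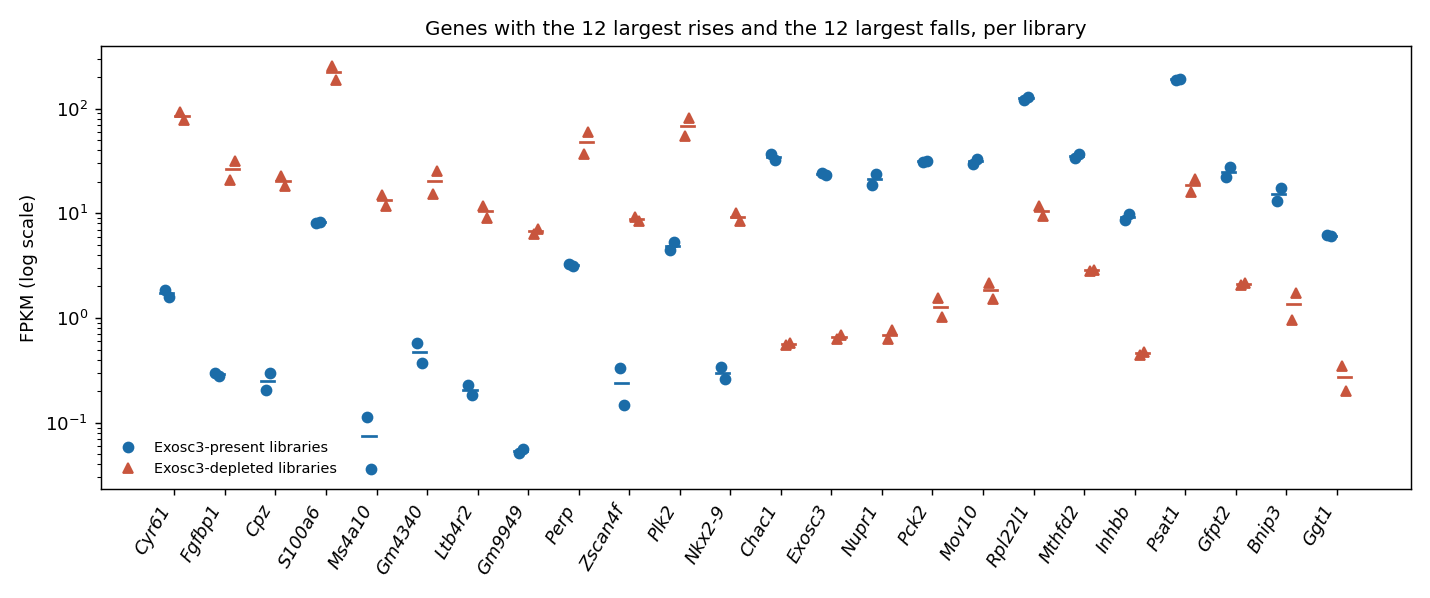
FPKM on a log axis of the 12 largest rises, left, and 12 largest falls, right; blue circles are Exosc3-present and red triangles Exosc3-depleted libraries, with a line at each mean of 2. Cyr61 moves from 1.86 and 1.60 to 92.2 and 77.4 FPKM, and Chac1 from 36.5 and 32.0 to 0.552 and 0.577.

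Targets of the tumour suppressor p53 were the gene list with the smallest p in Exosc3-depleted cells. Of 25 tested members 22 rose and 1 fell, or 23 and 1 adjusted over the list alone. Mdm2, the ubiquitin ligase that opposes p53, rose from 5.83 ± 0.39 to 56.1 ± 33.1 FPKM (log2 3.02), Cdkn1a, a cell cycle inhibitor, from 4.21 ± 0.28 to 15.7 ± 4.4 (1.75), and Ccng1 from 9.66 ± 0.16 to 54.6 ± 9.6 (2.43). Dcxr (2.88) and Btg2 (2.39), an antiproliferative gene, also rose. Sesn1 was the member that fell (log2 -0.98), and Polk (0.98) and Bax (0.44) did not pass. The list median was log2 1.71, or 1.98 relative to the median row (camera adjusted p = 1.06e-15; adjusted p = 0.339 with an estimated correlation). Between 17 and 24 members rose with any single library left out.

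Immediate early genes went both ways. Of 17 tested, 8 rose and 3 fell, with the same counts adjusted over the list alone. The transcription factor Jun rose from 1.32 ± 0.01 to 11.05 ± 0.25 FPKM (log2 2.66), Klf6 from 1.72 ± 0.11 to 20.04 ± 6.7 (3.17), Junb by log2 1.78 and Egr1 by 1.89, whereas Myc fell by 1.01 and Ier3 by 1.15. Camera put the list above other genes (adjusted p = 0.000529; adjusted p = 0.348 with an estimated correlation), with a median of log2 0.33. Of the 3 falls, 1 passed without Exosc3-present replicate 1 and 0 without Exosc3-present replicate 2.

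Exosc3-depleted cells held less RNA of many pluripotency genes and more of several early lineage genes. Of 25 pluripotency genes, 14 fell and 1 rose, or 15 and 2 adjusted over the list alone. Tcl1 fell from 44.9 ± 5.3 to 7.14 ± 0.78 FPKM (log2 -2.57), the growth factor gene Fgf4 from 35.0 ± 1.6 to 6.59 ± 0.52 (-2.33), the nuclear receptor gene Nr0b1 by 1.69 and the reprogramming factor gene Klf4 by 1.57. Gdf3 rose (0.67), and Pou5f1, the gene for OCT4, was at 452 ± 26 and 350 ± 90 FPKM (log2 -0.39, adjusted p = 0.167). The list's median was log2 -0.93, or -0.66 relative to the median row (camera adjusted p = 0.00597; adjusted p = 0.369 with an estimated correlation). Of 8 tested genes of the 2-cell-like state, 7 rose, also when adjusted over the list alone (camera adjusted p = 3.96e-09; adjusted p = 0.339 with an estimated correlation). Zscan4e went from 0.227 to 8.32 FPKM (log2 3.60), Zscan4c from 0.160 to 6.31 (3.37), Zscan4b from 0.197 to 6.16 (3.26) and Zscan4d from 0.060 to 4.03 (3.02). The Zscan4 copies are near identical, so the share of each is uncertain and they are not independent. Eif1a (log2 0.17) did not pass. The 7 that rose entered the test only through their rise, since with a filter on the Exosc3-present libraries alone Eif1a was the 1 member tested; with no filter on low values 17 of 25 rose and the list still passed.

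All 6 tested trophectoderm genes, of 14 with a row, rose, also adjusted over the list alone (camera adjusted p = 3.7e-06, and 0.369 with an estimated correlation). They were Krt7, Krt8, Krt18, Krt19, Ascl2 and Hand1, so the result speaks mainly for keratins. The transcription factor genes Cdx2, Elf5, Gata3 and Tead4 of the list were not tested. The estimated correlation within the list was 0.795, so its members are not independent. The keratins Krt19, Krt8 and Krt18 rose by log2 2.56, 2.29 and 1.97, with Krt8 going from 10.5 ± 0.39 to 54.2 ± 12.5 FPKM, and Hand1 rose by 1.46 to only 0.989 FPKM. The filter on mean FPKM admits low genes that rise: filtered on the Exosc3-present libraries alone 5 of 5 rose, without Hand1 (adjusted p = 1.84e-06), and with no filter on low values 7 of 12 rose and the list still passed. Of 14 primitive endoderm genes, 9 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 3.33e-05; adjusted p = 0.348 with an estimated correlation). The basement membrane collagens Col4a2 and Col4a1 rose by 2.24 and 1.96, Sparc by 1.36, and Sox17 rose by 0.94 to 0.902 FPKM, while Amn fell by 0.85. The number rising was 5 without Exosc3-present replicate 1 and 4 without Exosc3-present replicate 2, and 5 of 10 rose with the filter on Exosc3-present libraries. In the mesendoderm list, 5 of 7 rose and 2 fell, as they did adjusted over the list alone (camera adjusted p = 0.00614; adjusted p = 0.398 with an estimated correlation). Wnt3 rose from 0.033 to 1.86 FPKM (log2 2.14) and Nodal from 18.6 ± 0.75 to 42.8 ± 6.3 (1.18), while Lefty2, a Nodal antagonist, fell by 0.99 and did not pass without Exosc3-present replicate 2 (adjusted p = 0.102). The mesendoderm call ended with no filter on low values (7 of 16 rose, adjusted p = 0.111) and with the filter on Exosc3-present libraries (3 of 5, 0.0985). In the primed pluripotency and neural list, 6 of 10 rose and 2 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.0123; adjusted p = 0.398 with an estimated correlation). Neurod1 (2.73), the intermediate filament gene Nes (2.34) and Cdh2 (1.87) rose, and Tubb3, a neuronal tubulin, fell from 79.1 ± 2.9 to 21.5 ± 2.8 FPKM (-1.86). This list lost its call with scaling without the 50 highest genes (adjusted p = 0.0722), with the filter on Exosc3-present libraries (0.0892) and with the filter at a mean FPKM of 2 (0.0551), and 3 members rose without either Exosc3-present replicate. Of 13 germline genes 4 rose, led by Taf7l (0.574 to 3.87 FPKM), and 2 fell, led by the meiotic cohesin gene Stag3 (-1.71), with the same counts adjusted over the list alone (camera adjusted p = 0.103). The number of germline genes that rose was 1 without Exosc3-present replicate 1, and 5 fell without Exosc3-depleted replicate 2. The cells were grown without feeders, and of 6 tested fibroblast markers 2 rose and 1 fell, or 3 and 1 adjusted over the list alone (camera adjusted p = 0.0737). Thy1 fell from 2.24 to 0.179 FPKM (log2 -2.01), Twist1 (1.17) and Mmp2 (0.99) rose, and the abundant fibroblast transcript Col1a1 was at 0.438 and 0.771 FPKM (log2 0.42, adjusted p = 0.142). Without Exosc3-depleted replicate 2, 4 fibroblast markers rose and the list passed (adjusted p = 0.0226), as it did with no filter on low values (4 of 10 rose, 0.023), and 1 rose without Exosc3-present replicate 1.

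The list that joins the integrated stress response with the unfolded protein response was lower in Exosc3-depleted cells. Of 23 tested members 16 fell and 2 rose, also adjusted over the list alone (median log2 -1.16, camera adjusted p = 0.000273; adjusted p = 0.369 with an estimated correlation). Besides Chac1, Nupr1, Mthfd2 and Psat1, the serine synthesis enzyme Phgdh fell from 233 ± 11 to 38.4 ± 8.2 FPKM (log2 -2.60), the asparagine synthetase Asns from 299 ± 29 to 73.4 ± 8.1 (-2.02) and the transcription factor Atf4 from 128 ± 7.5 to 47.8 ± 3.4 (-1.41). Atf3 (1.76) and Ddit4 (1.10) rose. Glycolysis and hypoxia genes fell as well, 13 of 15 tested, or 14 adjusted over the list alone (median log2 -1.73, camera adjusted p = 1.13e-05; adjusted p = 0.369 with an estimated correlation). Pgk1 fell from 445 ± 53 to 71.8 ± 12.5 FPKM (log2 -2.63), Aldoa from 1218 ± 127 to 269 ± 46 (-2.19), the oxygen sensor gene Egln3 from 5.64 to 0.579 FPKM and the vascular growth factor gene Vegfa by log2 2.16. Gapdh (-0.45) and the glucose transporter gene Slc2a1 (-0.35) did not pass.

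Cell cycle genes were lower. Of 20 DNA replication and G1/S genes 17 fell, or 19 adjusted over the list alone (median log2 -1.02, camera adjusted p = 3.33e-05; adjusted p = 0.369 with an estimated correlation). Ccne1, which encodes cyclin E1, fell from 111 ± 11 to 18.8 ± 2.6 FPKM (log2 -2.54), and Cdc6, Uhrf1 and the clamp gene Pcna fell by 1.90, 1.82 and 1.45. Of 20 G2/M genes 14 fell, or 16 adjusted over the list alone (median log2 -0.98, camera adjusted p = 0.00146; adjusted p = 0.576 with an estimated correlation), among them the mitotic kinase gene Aurkb (-1.65), Ccnb2 (-1.43) and Cdk1 (-1.25). Without Exosc3-present replicate 2 the counts were 10 and 8, and with scaling without the 50 highest genes 11 and 8.

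Of 32 rRNA processing genes 12 fell, with the same count adjusted over the list alone, among them Nolc1 (-1.25), Rrp1b (-1.13) and Rrp1 (-1.07). The median was log2 -0.55, or -0.28 relative to the median row (camera adjusted p = 0.0385, and 0.635 with an estimated correlation). Of 46 cytosolic ribosomal protein genes 14 fell, or 13 adjusted over the list alone, led by Rps20 (-1.25) and Rpl10a (-1.08). The median was log2 -0.38, or -0.11 relative to the median row (camera adjusted p = 0.0331, and 0.786 with an estimated correlation). The share of ribosomal protein genes that fell was near the 30.8% of all protein-coding rows. Both calls ended with median-of-ratios scaling, where 4 and 2 members fell (adjusted p = 0.173 and 0.454), and where the other scalings gave 3 to 5 and 3 to 9. The filter at a mean FPKM of 2 (0.114 and 0.106) and that on Exosc3-present libraries (0.0985 for both) also ended both calls, limma-voom that of rRNA processing (0.0523) and a fit without an intensity trend that of ribosomal proteins (0.0572). For rRNA processing, 3 fell without Exosc3-present replicate 2 (adjusted p = 0.246), 5 without Exosc3-present replicate 1 (0.0712), 17 without Exosc3-depleted replicate 1 (0.113) and 24 without Exosc3-depleted replicate 2. For ribosomal proteins, 8 fell without Exosc3-present replicate 1 (0.162), 7 without Exosc3-present replicate 2, 31 without Exosc3-depleted replicate 1 and 17 without Exosc3-depleted replicate 2, where the list call also ended (0.991). Of 23 nuclear-encoded oxidative phosphorylation genes 6 fell, among them Cox5a (-1.05), and 1 rose, or 5 and 0 adjusted over the list alone (camera adjusted p = 0.448); 1 fell with median-of-ratios scaling or without either Exosc3-present replicate, and 14 without Exosc3-depleted replicate 1. Quantile normalization turned the balance, with 5 rising and 1 falling, and without Exosc3-depleted replicate 2 the counts were 3 and 10. The 13 mitochondrially encoded genes were not among the rows analysed here.

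Genes for RNA-processing factors were examined because the series concerns premature polyadenylation and its suppression by U1 snRNP, the splicing particle that binds 5′ splice sites. Of 12 U1 and core snRNP protein genes 7 fell, with the same count adjusted over the list alone. Snrnp70, which encodes the U1-70K protein, fell from 130 ± 9.2 to 63.0 ± 0.36 FPKM (log2 -1.04), and the Sm protein genes Snrpd3 and Snrpg fell by 1.16 and 1.11. The other U1-specific genes Snrpa (-0.42) and Snrpc (-0.38) did not pass, and the list was at adjusted p = 0.0775; 4 members fell with median-of-ratios scaling or quantile normalization, and 2 with scaling without the 50 highest genes, whereas the list passed with no filter on low values (adjusted p = 0.0155). Of 17 cleavage and polyadenylation factors 3 fell, all of them also adjusted over the list alone: Nudt21, from 101 ± 6.4 to 44.5 ± 2.3 FPKM (-1.18), the endonuclease gene Cpsf3 (-0.94) and Clp1 (-1.05) (camera adjusted p = 0.553). Without Exosc3-present replicate 2 only 1 of them passed, and without Exosc3-depleted replicate 2 the count was 8. Of 23 pausing and elongation factors 8 fell, or 6 adjusted over the list alone (camera adjusted p = 0.517), led by Rdbp, a negative elongation factor subunit (-1.07), and the histone chaperone gene Ssrp1 (-1.05). With median-of-ratios scaling 3 fell, and the count ran from 1 without Exosc3-present replicate 2 to 16 without Exosc3-depleted replicate 2, with 6 rising without Exosc3-depleted replicate 1.

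Of 8 Integrator genes 2 fell, Ints7 (-0.89) and Ints10 (-0.73), and both passed adjusted over the list alone (camera adjusted p = 0.348); of 13 nucleosome remodelers 3 fell, Chd4 (-0.98), Smarca4 (-0.78) and Smarce1 (-0.73), and 0 adjusted over the list alone (camera adjusted p = 0.502). Of 17 exosome cofactors 2 fell, the noncanonical poly(A) polymerase gene Papd7 (-0.86) and Zcchc8 (-0.63), and 0 adjusted over the list alone (camera adjusted p = 0.787). Under the other scalings 1 to 2 cofactors rose and 0 to 1 fell. The list holds Mpp6, which in mouse names a membrane-associated guanylate kinase; without it 2 of 16 fell (camera adjusted p = 0.883). Of 20 genes of cytoplasmic and 5′-to-3′ decay 2 fell, the deadenylase genes Cnot8 (-1.13) and Pan2 (-0.56), or 1 adjusted over the list alone (camera adjusted p = 0.711). Camera placed this list above other genes although its median (log2 -0.08) was negative. Under the other scalings 1 to 3 decay genes rose and 1 fell. With median-of-ratios scaling 0 Integrator genes and 0 remodelers fell, and without Exosc3-depleted replicate 2 the numbers that fell were 4 Integrator genes, 10 remodelers, 11 cofactors (10 without Mpp6) and 10 decay genes. Without Exosc3-depleted replicate 1, 3 cofactors and 5 decay genes rose, and without either Exosc3-present replicate 0 Integrator genes and 0 cofactors fell.

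Heat shock genes went both ways. Of 14 tested, 7 fell and 3 rose, or 8 and 3 adjusted over the list alone (camera adjusted p = 0.713): Hsp90ab1, a cytosolic chaperone gene, fell from 1690 ± 215 to 841 ± 26 FPKM and Ahsa1 by log2 1.22, while the inducible Hspa1a rose from 5.22 ± 0.59 to 11.98 ± 0.62 (1.13). Hspa1a did not pass without Exosc3-present replicate 1 (adjusted p = 0.0627), where 0 members rose, and 4 fell and 1 rose without Exosc3-present replicate 2. With quantile normalization or scaling without the 50 highest genes 3 heat shock genes fell and 4 rose. Of 11 interferon-stimulated and RNA-sensing genes 6 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 0.113). Stat2 fell from 4.65 to 0.976 FPKM, Bst2 by log2 1.39 and Ifitm1 by 1.32; 3 fell without either Exosc3-present replicate.

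**Figure D3:**
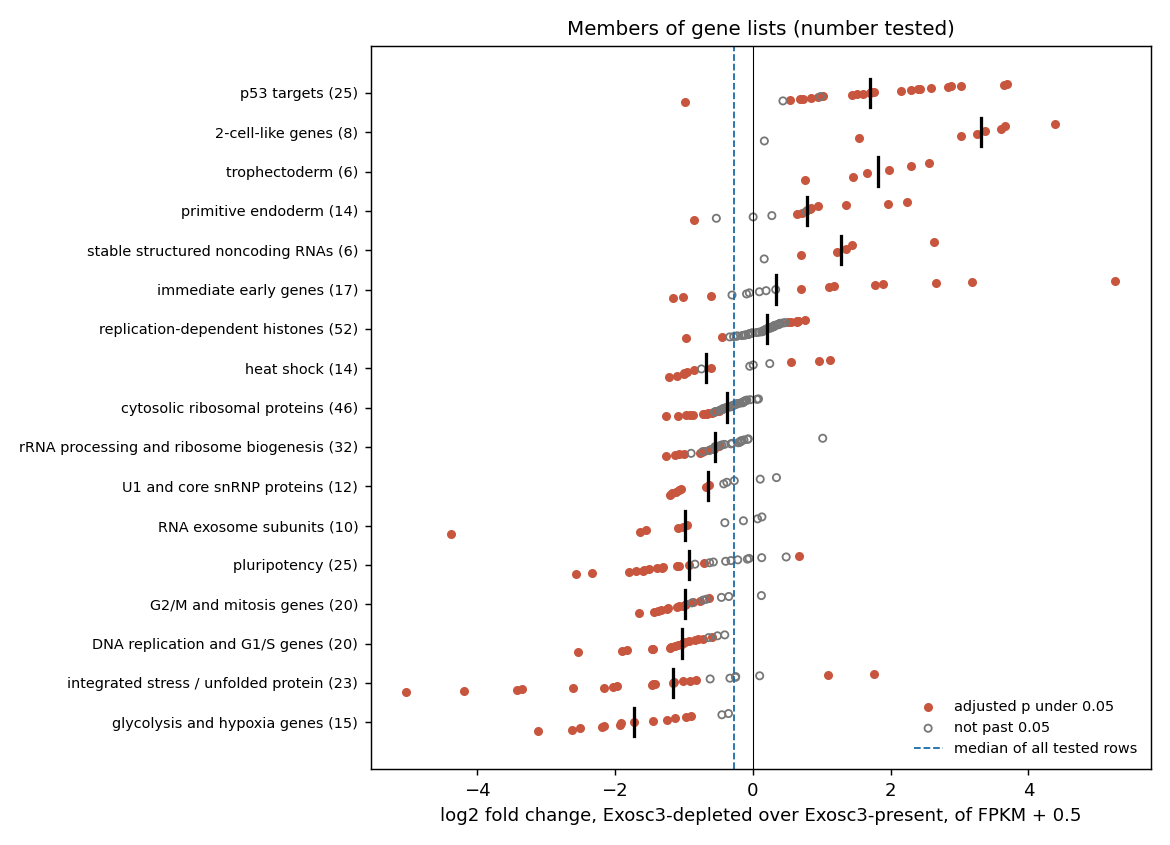
Log2 fold change of FPKM plus 0.5 for each tested member of 17 gene lists; red points passed an adjusted p of 0.05, open points did not, black bars are list medians and the dashed line is the median of all tested rows (-0.27). Medians run from 3.31 in the 2-cell-like list to -1.73 in the glycolysis and hypoxia list.

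The next comparison asked whether noncoding RNAs, among them known exosome substrates, changed more than messenger RNAs. Most tested members of the list of structured noncoding RNAs were higher in Exosc3-depleted cells. Of 34 members 8 had a row and 6 were tested, of which 5 rose, also adjusted over the list alone. The camera adjusted p was 3.33e-05, and 0.348 with an estimated correlation. Rnu12 and Rnu11, snRNAs of the minor spliceosome, rose from 51.7 ± 1.6 to 322 ± 15 FPKM (log2 2.63) and from 2014 ± 126 to 4679 ± 223 (1.22), and the telomerase RNA Terc rose from 835 ± 104 to 2118 ± 82 (1.35). The RNase MRP RNA Rmrp rose by 0.70 and the Rn4.5s row by 1.44. The Rn4.5s model of 1740 bases, at 0.0936 and 1.12 FPKM, is longer than that RNA. Rpph1, the RNase P RNA, was at log2 0.17 (limma adjusted p = 0.556). Outside the list, the snRNA row Rnu1b2 rose by 2.44. A further RNase P row, Rprl3 (log2 0.04, adjusted p = 0.89), and the abundant Vaultrc5 row (0.01, adjusted p = 0.982) did not pass. Of 5 tested long noncoding and microRNA host RNAs 3 rose, or 4 adjusted over the list alone (camera adjusted p = 0.0121; adjusted p = 0.369 with an estimated correlation). The imprinted Meg3 rose from 3.00 ± 0.12 to 13.7 ± 2.3 FPKM (2.01), Dleu2 by 0.98 and Tug1 by 0.82; 1 rose without Exosc3-present replicate 1, where Dleu2 (adjusted p = 0.069) and Tug1 (0.245) did not pass. Tug1 also did not pass without Exosc3-present replicate 2 (0.129) or with no filter on low values (0.0952). Of 2 tested snoRNA host genes, Taf1d rose (0.62) but did not pass without either Exosc3-present replicate (adjusted p = 0.212 and 0.286), and Snhg3 was at 0.50 (adjusted p = 0.0579); both passed adjusted over the list alone.

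Replication-dependent histone genes, whose messenger RNAs end in a stem-loop in place of a poly(A) tail, were slightly above other genes. Of 52 tested 7 rose and 2 fell, but 1 and 1 adjusted over the list alone (median log2 0.21, or 0.48 relative to the median row; camera adjusted p = 4.81e-05; adjusted p = 0.348 with an estimated correlation). Hist2h2aa2 rose by 0.76 and Hist2h3c1 by 0.64, while the linker histone gene Hist1h1b fell from 1111 ± 58 to 569 ± 59 FPKM (-0.97), a call that ended with median-of-ratios scaling (-0.65, adjusted p = 0.0519), where 0 histone genes fell. The number rising was 21 with median-of-ratios scaling and 31 without the 50 highest genes in the scaling, and it ran from 1 without Exosc3-present replicate 1 to 15 without Exosc3-depleted replicate 1. Histone copies share sequence, so fragments could be assigned to the wrong copy.

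By annotation, 54 of 90 tested noncoding rows rose and 12 fell (13.3%), against 973 (11.1%) and 2705 (30.8%) of 8774 protein-coding rows. The long noncoding RNAs gave 43 rises and 7 falls among 69 tested, whereas of 9 microRNA rows 3 rose and 4, all copies of Mir684-1, fell. Of 3 rows under snoRNA symbols 2 rose and the Snora24 row fell by log2 1.37 (adjusted p = 0.00123), but the models of Snora24 (785 bases) and Snora17 (1475 bases) are longer than a snoRNA and do not measure it alone. B930059L03Rik, for example, rose from 0.738 ± 0.024 to 4.80 ± 0.67 FPKM (log2 2.09) and C130036L24Rik from 1.98 ± 0.01 to 10.1 ± 0.05 (2.09). The odds ratio of a rise was 12.02 (95% interval 7.70 to 18.96; two-sided Fisher's exact p = 2.23e-28), and that of a fall 0.345 (0.171 to 0.639; p = 0.000195). Against 879 coding rows matched on mean FPKM the odds ratio of a rise was 8.77 (5.41 to 14.4). As a group the noncoding rows were above other genes, at a median of log2 0.91 against -0.28 for coding rows. The camera p was 5.52e-16, and 0.0394 with an estimated correlation. Camera p-values of this group are not adjusted over lists, unlike those of the gene lists. A rise could itself bring a row past this filter; of 65 noncoding rows filtered on the Exosc3-present libraries alone 29 rose, and the median was 0.50 (camera p = 5.13e-09; p = 0.0715 with an estimated correlation). Genes are not independent replicates, so these p-values describe the table. By Fisher's exact test the odds ratio of a fall was no longer past 0.05 with median-of-ratios scaling (0.594, p = 0.125), without the 50 highest genes in the scaling (p = 0.0711), with scaling to fragments within listed genes (p = 0.0831), with a length trend removed (p = 0.0701), with the filter at a mean FPKM of 2 (p = 0.067), against coding rows filtered and matched on the Exosc3-present libraries (0.661, p = 0.23), or without Exosc3-present replicate 1 (p = 0.174) or 2 (p = 0.183). The odds ratio of a rise was 7.14 without Exosc3-depleted replicate 1, 7.48 with a length trend removed and 3.99 with no filter on low values.

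**Figure D4:**
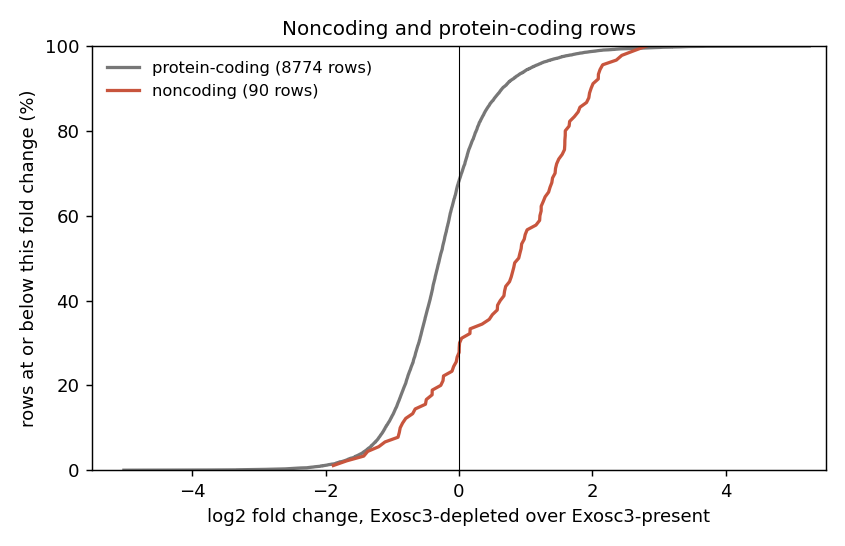
Cumulative share of rows (%) at or below each log2 fold change for 90 noncoding (red) and 8774 protein-coding (grey) rows. The noncoding curve lies to the right through most of its range, with a median of 0.91 against -0.28.

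The last comparison asked whether the change followed gene length, since premature polyadenylation lies near the start of genes. The fold change showed little relation to genomic span over 8919 rows (Spearman's rho = -0.020, permutation p = 0.0623, 100000 permutations; across genes, which are not independent replicates). The median log2 fold change was -0.19 in the shortest of 5 equal bins (median span 4.0 kb), then -0.33, -0.36 and -0.31, and -0.21 in the longest (99.1 kb). The 2 Exosc3-depleted libraries disagreed here. Replicate 2 minus replicate 1 had a median of log2 -0.17 in the shortest bin and 0.45 in the longest (rho = 0.491 over genes), against 0.00 and 0.11 for the Exosc3-present libraries (rho = 0.269). Without Exosc3-depleted replicate 1 rho became 0.117, and without Exosc3-depleted replicate 2 it became -0.170, so no direction with length was shared by both Exosc3-depleted libraries. Whole-gene FPKM values do not separate the start of a gene from its end, so premature polyadenylation itself was not measured here.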

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

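These signals outside the tested rows were looked for after the results were seen, and no explanation was tested for them. Listed gene models left 57.6% and 56.0% of the per-million total unaccounted for in the Exosc3-depleted libraries, against 50.3% and 48.2% in the Exosc3-present libraries. Which fragments were counted in that total is not recorded, and no mitochondrially encoded genes are among the rows, so what this remainder holds is not known. Among 13547 rows too low to be tested, 55 had at least 3 fragments in both Exosc3-depleted libraries and 0 in both Exosc3-present libraries, and 37 showed the reverse although the Exosc3-present libraries were deeper. The 55 included Kynu, a kynurenine pathway gene, with 26 and 42 fragments, and Clca3 with 17 and 47. They also included the transcription factor gene Tcfap2b with 10 and 17. These examples were chosen after their values were seen. All rows of both kinds were above 0 in the libraries of a single group, so their recovered lengths and fragment counts are not secured. The cut at 3 fragments, the numbers 55 and 37 and the fragments of the examples are therefore uncertain. The values of 0 do not rest on that recovery.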

How the results depend on the processing

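Tests with limma-voom, scaling to fragments within listed genes, removal of a length trend, a filter on the Exosc3-present libraries and lists without 1 member were chosen after the data were seen. Over 17 other fits, 0 rows called both there and in the main test changed sign. That outcome was nearly fixed in advance, because the same data entered all these fits. Exosc3 passed in all of them, with a log2 fold change between -5.14 and -3.89 (-4.42 to -4.35 with single libraries left out), and the noncoding odds ratio lay between 3.99 and 12.5 (7.14 to 15.4). A mean FPKM of at least 2, which tests fewer rows, left 667 rows higher and 10 lists past the threshold, the filter on Exosc3-present libraries left 12 lists, and removing a length trend gave 2105 rows higher. Rows lower numbered 1589 with median-of-ratios scaling, 1782 with quantile normalization, 1330 without the 50 highest genes and 1828 with scaling to fragments within listed genes, because these scalings move the median row. The changed rows numbered 1827 at an absolute log2 fold of at least 1 and 2201 at an adjusted p under 0.01. With single libraries left out 1750 to 6334 rows changed, 668 to 2183 higher and 1082 to 4715 lower, and 16 to 17 lists passed. No list passed with an estimated correlation (0), and 28 passed a mixed fry test, which asks another question. Directional fry called 16 lists: it added U1 and core snRNP (adjusted p = 0.02), Integrator (0.0478) and interferon (0.0219), and lost long noncoding RNAs (0.0713), primed and neural genes (0.104), rRNA processing (0.0956), ribosomal proteins (0.146) and G2/M genes (0.0767).

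The relation with gene length stayed weak but had a permutation p under 0.05 in these alternatives: rho was -0.029 (pseudocount 0.1), -0.044 (filter at 2), -0.033 (median of ratios), -0.052 (quantile), -0.032 (without the 50 highest), -0.032 (limma-voom), -0.029 (fragments within listed genes) and -0.042 (length trend removed). With single libraries left out rho ran from -0.170 to 0.117, and without Exosc3-present replicate 2 it was 0.014 (p = 0.202). Of the lists that passed, the cytosolic ribosomal proteins changed sign (relative median 0.183 without Exosc3-depleted replicate 2, where they no longer passed). The other changes of sign concerned lists and genes that did not pass, and apart from the scaling itself the cause was not tested. Relative medians of the exosome cofactors were 0.067 (filter at 2), 0.026 (median of ratios), 0.078 (quantile), 0.027 (without the 50 highest), 0.017 (fragments within listed genes), 0.003 (length trend) and 0.047 with the filter on Exosc3-present libraries, and those of decay genes -0.039 with no filter; directional fry named decay genes lower from the same plain median (-0.081) as in the first test. Quantile normalization gave 0.052 for cleavage and polyadenylation factors and 0.132 for oxidative phosphorylation genes. Exosc5 was at 0.183, 0.259, 0.206, 0.096 and 0.173 under median of ratios, quantile, without the 50 highest, fragments within listed genes and length trend. With single libraries left out the ranges were -0.145 to 0.055 for cofactors, -0.042 to 0.099 for cleavage factors, -0.294 to 0.174 for remodelers, -0.264 to 0.251 for oxidative phosphorylation genes, -0.065 to 0.204 for Exosc10 and -0.081 to 0.347 for C1d. For pausing factors (-0.111 to -0.044) and decay genes (0.003 to 0.342) only the direction named by camera changed, not the sign of the relative median.

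Replicate numbers do not pair these samples by any label, and with 2 pairs the correlation of same-numbered deviations (0.244) is no proof of pairing. With the replicate number as a block 4899 rows changed (1431 higher, 3468 lower) and 16 lists passed, with rRNA processing (adjusted p = 0.124) and ribosomal proteins (0.1) losing their call, Exosc3 was at -4.38, the noncoding odds ratio at 11.5 and rho with length at -0.020. Depth limits low genes most: in the Exosc3-depleted libraries a 1 kb model needs 0.0262 and 0.0238 FPKM for 1 fragment.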

Other observations

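Apart from the use of median-of-ratios scaling, the tests in this part were chosen after the results were seen. They use the same data, so each gives a hypothesis at most. Camera p-values in this part are not adjusted over lists, so they cannot be set against the adjusted values of the fixed lists. A group of genes often used as readouts of YAP and TEAD transcription was higher in Exosc3-depleted cells. Of 16 listed genes 11 were tested, of which 8 rose and 1 fell, or 9 and 1 with median-of-ratios scaling. Camera gave p = 5.89e-06, and p = 0.216 with an estimated correlation. The list was chosen because of Cyr61, and without it 7 of 10 rose and 1 fell (camera p = 9.04e-05; p = 0.315 with an estimated correlation). Besides Cyr61, the matrix protein gene Thbs1 rose from 0.037 to 4.64 FPKM (log2 3.20), Amotl2 by 1.85, Myof by 1.64 and the receptor gene Axl by 1.30, while Fstl1 fell by 1.09. Whether a YAP-TEAD programme was raised stays open, since the p-value rests on the assumed correlation and the filter admits low genes that rise; Cyr61 also stands in the immediate early list.

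Rows with no match in the annotation, mostly named by clone accessions, rose more often than coding rows. Of 417 such rows 139 rose and 71 fell (odds ratio of a rise 4.01, 95% interval 3.21 to 4.99; Fisher's exact p = 1.26e-31), but a rise could itself bring a low row past the filter. Filtered on the Exosc3-present libraries alone, 71 of 350 rose and 78 fell, and the odds ratio against 2691 coding rows matched there was 2.44 (1.797 to 3.287; Fisher's exact p = 1.23e-08). They may hold further unstable noncoding transcripts, which the table cannot show. A related hypothesis, that long noncoding RNAs starting within 1 kb of a coding gene's start on the other strand rise more often, was left open. Of the 69 tested long noncoding RNAs 49 could be placed in the annotation. Of the 17 with such a start 13 rose, against 17 of the 32 others placed (Fisher's exact p = 0.135).

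Genes associated with the transcription factor ATF4 and amino acid supply fell widely. Of 41 listed 31 were tested, of which 25 fell and 3 rose (median log2 -1.46). The unadjusted camera p was 1.61e-07, and 0.0327 with an estimated correlation. That list holds the falls that prompted it; without the 12 largest falls 20 of 26 fell and 3 rose (camera p = 4.46e-05; p = 0.0495 with an estimated correlation). Without the members of the fixed lists too, among them all 3 that rose, 13 of the 15 genes left fell (camera p = 9.13e-06; p = 0.0418 with an estimated correlation). Among these 15 were the aminoacyl-tRNA synthetases Nars (-2.38) and Sars (-2.04), the alanine transaminase Gpt2 (-2.93) and the proline enzyme Pycr1 (-2.30). The scaling of FPKM alone is argued against, since 23 of the 31, and 11 of the 15, still fell after median-of-ratios scaling. A stress response that lowered endoplasmic reticulum chaperone genes by a like amount is argued against, since the median of those 15 genes was below that of 20 chaperone genes (log2 difference -0.984, permutation p = 9e-05). Over all 31 genes the difference was -1.003 (permutation p = 0.00343). Fixed-list members, among them all 3 that rose, were left out on the ATF4 side only. The permutation swaps genes, which are not independent replicates, so both p-values describe the gene lists. Of the chaperone genes 8 fell, or 3 with median-of-ratios scaling (camera p = 0.0646; p = 0.376 with an estimated correlation). A shared response of unequal size is not excluded. Whether the fall came from loss of Exosc3 or from removing doxycycline, which inhibits mitochondrial translation and could raise these genes in Exosc3-present cells, cannot be told apart, because 0 groups change doxycycline without Exosc3. A culture kept in or out of doxycycline with constant Exosc3 would decide it.

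The rise of noncoding rows was set against 3 technical explanations. Scaling is argued against by an odds ratio of 9.59 (6.06 to 15.5) with median-of-ratios scaling, and low expression by 6.35 (3.51 to 11.5), from 65 noncoding and 580 coding rows filtered and matched on the Exosc3-present libraries alone, so that a rise could not bring a row in. With no filter on low values the ratio was 3.99. Reads spilling from neighbouring coding genes that themselves rise are argued against. Around the 30 of 43 risen long noncoding RNAs that could be placed, 23 tested coding genes lay within 10 kb. Their median log2 fold change was -0.08 (95% bootstrap interval -0.34 to 0.06), and 0 rose and 6 fell, while those 30 RNAs rose by a median of 1.59. Read-through from a neighbour whose own level stayed flat is not covered, nor are RNAs without a tested neighbour, and strand was not considered. Stabilisation of noncoding RNA after loss of the exosome is a hypothesis that these values allow and the shared change in doxycycline leaves untested; RNA half-lives with doxycycline held constant would test it.

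The 2 Exosc3-depleted libraries differed by gene length, with rho of 0.491 between genomic span and replicate 2 minus replicate 1. Thinning all libraries to 16150958 fragments left rho at 0.491 but removed few fragments from these 2 libraries, so it does not decide on depth. In 235 genes whose span exceeded the model length by at most 10 bases, rho with model length was 0.223 (0.098 to 0.336). Span and model length come from different annotations, and models longer than the span also count here. These genes are therefore not shown to lack introns, and intron length alone is not excluded. Mature transcript length alone is argued against by rho of 0.317 (0.278 to 0.357) with intron length within 1792 genes of similar model length. No biological explanation was tested because both libraries belong to 1 group; RNA integrity above the stated minimum RIN of 8.5 or the share of unspliced RNA may differ between them, and the labels give neither per library.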
